A study of Drosophila melanogaster with 4 samples.

How the data were processed

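The measurement was polyA RNA sequencing of GFP-positive cells sorted from stage 11 Drosophila melanogaster embryos of 2 lines, wild type (WT) and homozygous salm[340], with 2 libraries per line. Per the labels' protocols, eggs were laid on grape agar for 3 h at 25 C and aged for 7 h, homozygous embryos were picked by their GFP under a fluorescence microscope, dissociated with elastase, and the GFP-positive cells were sorted before RNA extraction with a Qiagen RNeasy kit. The series describes the replicates as technical, so p-values measure only the spread between these libraries. Libraries were built by a commercial provider, per the labels' protocols, and a strand setting is not given in the sources used here.

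Reads were trimmed and aligned to build BDGP6 with tools that include cutadapt 2.4 and STAR 2.5.4b, per the submitters' processing notes. The authors counted fragments per gene with featureCounts 2.0.1 against the Ensembl BDGP6.32 annotation of release 104, per the file headers. The deposited values are raw counts, not normalized. Per the file headers, multi-mapping fragments and fragments overlapping several features were counted for every feature they touched, both mates had to align to the same chromosome, and at least 10 bases had to overlap. Strand was not used. Counts of near-identical copies (Hsp70, histone, rRNA, Cyp4p and Prx2540 genes, transposons), of overlapping genes and of antisense partners therefore share fragments and are uncertain as single genes.

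The per-library files hold 23882 features each, and the table of the whole series lists 17518 of them as genes with names, types and positions. The counts of all 17518 listed genes were equal in both sources. The features outside that table are 6052 transposon insertions and 312 tRNA genes, which hold 5.78% to 6.35% of the counts and stayed out of the gene test. Totals over the listed genes were 21857295 and 20530119 for WT replicates 1 and 2, and 15170218 and 15668621 for salm[340] replicates 1 and 2. Without mitochondrial genes, 16444569 and 14519441 counts remained in WT and 5931283 and 5772320 in salm[340], so nuclear genes were measured less deeply in the mutant libraries. Positions are those of the deposited gene table. No genome sequence was used here, and GC content was not analysed here.

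Groups were taken from the titles and genotype labels. Each comparison is salm[340] against WT on all 4 libraries, fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit without robust estimation, glmQLFTest) without a replicate block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A log2 fold change is salm[340] minus WT, its standard error is the absolute log2 fold change divided by the square root of F, and CPM values use the TMM effective library sizes. TMM factors were 1.55 and 1.47 in WT and 0.675 and 0.649 in salm[340]. Every fold change is therefore relative to the bulk of genes, and not an amount of RNA per cell. The common dispersion was 0.0156.

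The lists were fixed before the data were examined: 26 lists with 499 entries, of which 490 matched by symbol, 6 by a synonym and 3 not at all. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on log2 CPM with a prior count of 2. Shares of called genes per chromosome arm, and within 2 Mb of salm against the rest of 2L, were tested with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The rule for named genes, also fixed before the data were examined, took salm and salr, the 12 largest changes in each direction among called genes with a mean of at least 10 CPM in the higher line and both libraries of one line above both of the other, and up to 4 members of each list with the smallest adjusted p. Other genes are named as members of small counts and were chosen after their values were seen.

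Replicate libraries were compared by a chi-square over genes with at least 10 counts. The chi-square per degree of freedom was 13.3 for the WT pair and 10.3 for the salm[340] pair (4.15 and 7.36 over nuclear genes), so the libraries of a pair differed by more than counting noise. Separate libraries of one RNA would do so as well, and the sources used here do not state whether the replicates are separate sorts or libraries of one RNA. Each n of 2 therefore counts libraries.

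The test was tried on simulated counts with the means, library sizes and dispersions of the 10738 genes tested and 200 genes changed by known amounts. For this comparison it recovered 57 of 96 genes changed by 1 on the log2 scale (59.4%) and 87 of 98 changed by 2 (88.8%), and 3.36% of its 149 calls were unchanged genes. In this simulation, changes near a doubling were therefore often missed. It changed fewer genes than the 1847 called in the data and gave both lines the same dispersions, so its shares need not hold for the data.

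Alternatives tried were size factors of DESeq2 within edgeR, upper-quartile scaling, library size without scaling factors, the Wald test of DESeq2 1.42.0, limma-voom, other count filters, the replicate number as a block, glmTreat, and each library left out in turn. After seeing the data, fits without mitochondrial genes, without mitochondrial and rRNA genes, on nuclear protein-coding genes only and on nuclear counts thinned to the smallest library were added, and the arm test without histone genes.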

Results

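Embryonic myoblasts, the cells that fuse into the larval body wall muscles, were profiled in 2 Drosophila lines, WT and salm[340], a mutant allele of spalt major (salm). The series asks which genes depend on Salm, a zinc finger transcription factor, during muscle formation. Each line had 2 libraries, described by the submitters as technical replicates, so n counts libraries and not known separate sorts. Counts in listed genes were 21857295 and 20530119 per library in WT and 15170218 and 15668621 in salm[340]. The libraries of the lines differed in composition. Mitochondrial genes took 24.8% and 29.3% of the counts in WT and 60.9% and 63.2% in salm[340], most of it from the large mitochondrial rRNA (20.2% and 24.1% against 48.1% and 49.6%). Nuclear rRNA features took 0.768% and 0.591% of nuclear counts in WT and 2.60% and 2.51% in salm[340].

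**Figure D1:**
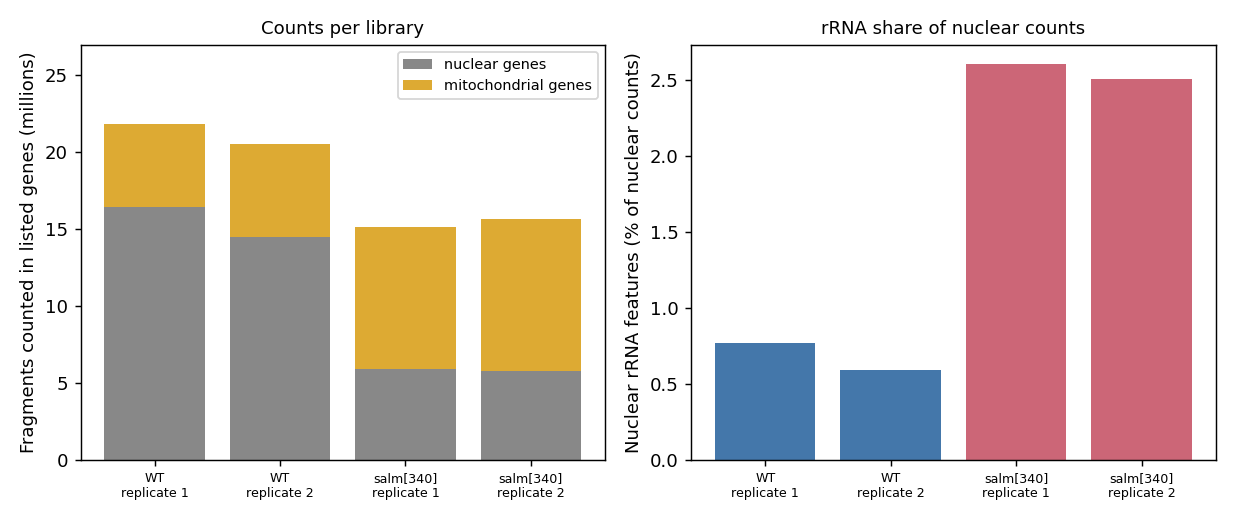
Left, counts in nuclear and mitochondrial genes (stacked bars) in each of the 4 libraries. Right, nuclear rRNA features as a percentage of nuclear counts in each library. Mitochondrial genes took 60.9% and 63.2% of the counts in the salm[340] libraries against 24.8% and 29.3% in WT.

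The RNA of salm itself (FBgn0261648, 2L, 11434311 to 11445614, minus strand, BDGP6) was higher in the libraries labelled salm[340]. Its counts were 871 and 749 in WT and 954 and 994 in salm[340]. Scaled, salm rose from 25.2 ± 0.602 CPM (SD, n = 2) in WT to 95.5 ± 3.22 CPM (SD, n = 2) in salm[340], a log2 fold change of 1.92 (SE 0.0926, edgeR adjusted p = 1.102e-06). The labels do not say what the allele changes, so the level of its RNA does not check them. The neighbouring paralog spalt-related (salr, 2L, 11358873 to 11373636) rose as well, from 14.6 ± 1.73 to 44.6 ± 5.62 CPM (SD, n = 2 each, log2 fold change 1.62, SE 0.140, edgeR adjusted p = 5.571e-05). Both rises were larger than the shift of -1.19 that library size alone gives the median gene, and both kept their direction there. Without either WT library the salm difference stayed near that size, at 1.94 without WT replicate 1 and 1.89 without WT replicate 2, but no longer passed (edgeR adjusted p = 0.0984 and 0.0873).

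Across the transcriptome, 1847 of 10738 tested genes were called between the lines, 1078 higher and 769 lower in salm[340], and 550 of them differed at least 2-fold (326 higher, 224 lower). The number depended on which libraries gave the spread. Without WT replicate 1 or without WT replicate 2, the count was 14, the same 14 genes each time, all of them higher: CG5071, CG11825, Cyp4p1, Cyp4p2, 8 mitochondrial transcripts and 2 28S rRNA pseudogenes, named after their values were seen (1269 and 1277 genes had an unadjusted p under 0.05). It was 3803 without salm340 replicate 1 and 3602 without salm340 replicate 2. In each of these fits the lone library was assumed to vary like the pair of the other line. The split by direction depended on the scaling. With library size alone, the median gene moved by -1.19 on the log2 scale and 8361 genes were called, 84 higher and 8277 lower (1.0% higher against 58.4% with TMM). Library size counts the mitochondrial genes, which took more of the counts in salm[340]. With either scaling a rise is thus relative to other genes.

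Apart from rRNA features and mitochondrial transcripts, the 12 largest rises came from genes that averaged at most 1.48 CPM in WT. The cytochrome P450 genes Cyp4p2 and Cyp4p1, which lie side by side on 2R (9237512 to 9239831 and 9240041 to 9242139), went from 0.0663 ± 0.0937 to 63.5 ± 0.608 CPM and from 0.144 ± 0.0781 to 44.5 ± 0.0671 CPM (SD, n = 2 each). Their log2 fold changes were 9.86 (SE 0.312) and 8.25 (SE 0.247), with edgeR adjusted p of 8.465e-08 and 8.036e-08, and as paralogs they may share fragments. CG11825 (2R, 10420414 to 10423650) rose by 7.996 (SE 0.161) to 105.0 ± 0.693 CPM, and CG5071 (3R, 25618414 to 25621838) by 7.00 (SE 0.117) from 1.48 ± 0.0319 to 190.6 ± 2.93 CPM (SD, n = 2 each). CG13083 (log2 fold change 5.41), ChLD3 (4.59) and lncRNA:CR44977 (3.36), all on 2L, were also among the 12. The rest of the 12 were the rRNA features 28SrRNA-Psi:CR45860 (4.83), 5.8SrRNA:CR40454 (3.23) and 5.8SrRNA-Psi:CR45854 (2.98), and the mitochondrial transcripts mt:ATPase8 (2.96) and mt:ND4L (2.86). All 16 mitochondrial transcripts tested were higher (median 2.60), as were 11 of 12 nuclear rRNA features (median 2.09).

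Among the largest falls, lncRNA:CR45247 and CG42831, neighbours on 3L (10816581 to 10817182 and 10814819 to 10816084), dropped from 28.1 ± 1.86 to 0.491 ± 0.280 CPM and from 16.2 ± 0.335 to 0.293 ± 0.415 CPM (SD, n = 2 each). Their log2 fold changes were -5.83 (SE 0.288) and -5.76 (SE 0.495). The zinc finger transcription factor gene rotund (rn, 3R, 7272617 to 7309629) had 438 and 478 counts in WT and 1 and 5 in salm[340], a log2 fold change of -5.58 (SE 0.430, edgeR adjusted p = 2.948e-05). CG11883 (-4.05), the leucokinin receptor gene Lkr (-3.91), CG7910 (-3.88) and Cyp4g1, a cytochrome P450 gene of oenocytes (-3.53, from 17.7 ± 2.38 to 1.52 ± 0.909 CPM, SD, n = 2 each), came next. CG8907 (-2.91), CG10268 (-2.65), the peroxiredoxin gene Prx2540-2 (-2.56), Ady43A (-2.32) and the chitin synthase gene Chs2 (-2.24) completed the 12. Prx2540-2 has close paralogs and its value is uncertain. Library size alone shifts the median gene by -1.19, a smaller shift than the smallest of the 12 rises (2.86). The direction of the 24 largest changes in that setting was thus close to fixed in advance. All 24 of these genes kept their direction with library size alone, and 4 of the 24 were called without either WT library.

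**Figure D2:**
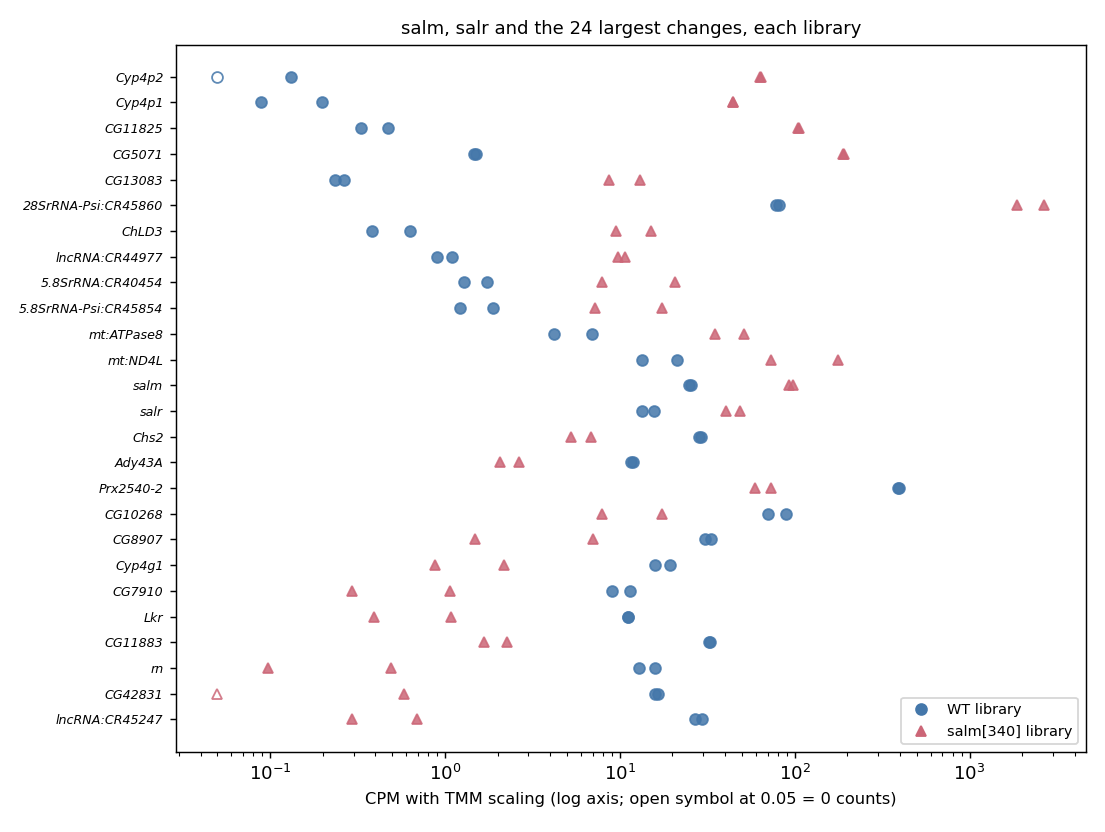
CPM with TMM scaling (log axis) of salm, salr and the 24 largest changes in each library, circles for WT and triangles for salm[340], with open symbols for 0 counts. Both libraries of one line lie above both of the other for every gene shown, and Cyp4p2 goes from 0.0663 to 63.5 CPM on average.

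Many genes of the contractile apparatus rose. Of 29 tested sarcomere and contractile genes, 22 were higher in salm[340], 11 of them at least 2-fold, 1 was lower and 6 did not pass (22 higher and 1 lower adjusted over the list alone). The median log2 fold change was 0.72. Muscle myosin heavy chain (Mhc) went from 322.4 ± 2.15 to 786.7 ± 0.525 CPM (log2 fold change 1.29, SE 0.0684), the troponin T gene upheld (up) from 215.4 ± 7.39 to 610.0 ± 49.3 CPM (1.502, SE 0.0813), the muscle LIM protein gene Mlp60A from 33.3 ± 1.06 to 108.1 ± 11.7 CPM (1.70, SE 0.101), and the myosin regulatory light chain gene Mlc2 from 231.1 ± 4.35 to 495.2 ± 25.2 CPM (1.10, SE 0.0743; SD, n = 2 each, edgeR adjusted p between 2.246e-06 and 1.414e-05). The troponin C gene TpnC41C was the member that fell (-2.22, 2.30 to 0.491 CPM). Camera placed the list above other genes at the preset correlation (adjusted p = 5.7e-09), and this was lost with an estimated correlation (adjusted p = 0.822). Fry, which tests the list against no change, did not pass (adjusted p = 0.0652). The mitochondrial share of counts was higher in the same libraries. With library size alone, 2 members were called higher and 15 lower in edgeR. Without WT replicate 1 or WT replicate 2, 0 members passed in edgeR, while 19 and 20 were higher at an unadjusted p under 0.05 and the medians were 0.77 and 0.67.

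**Figure D3:**
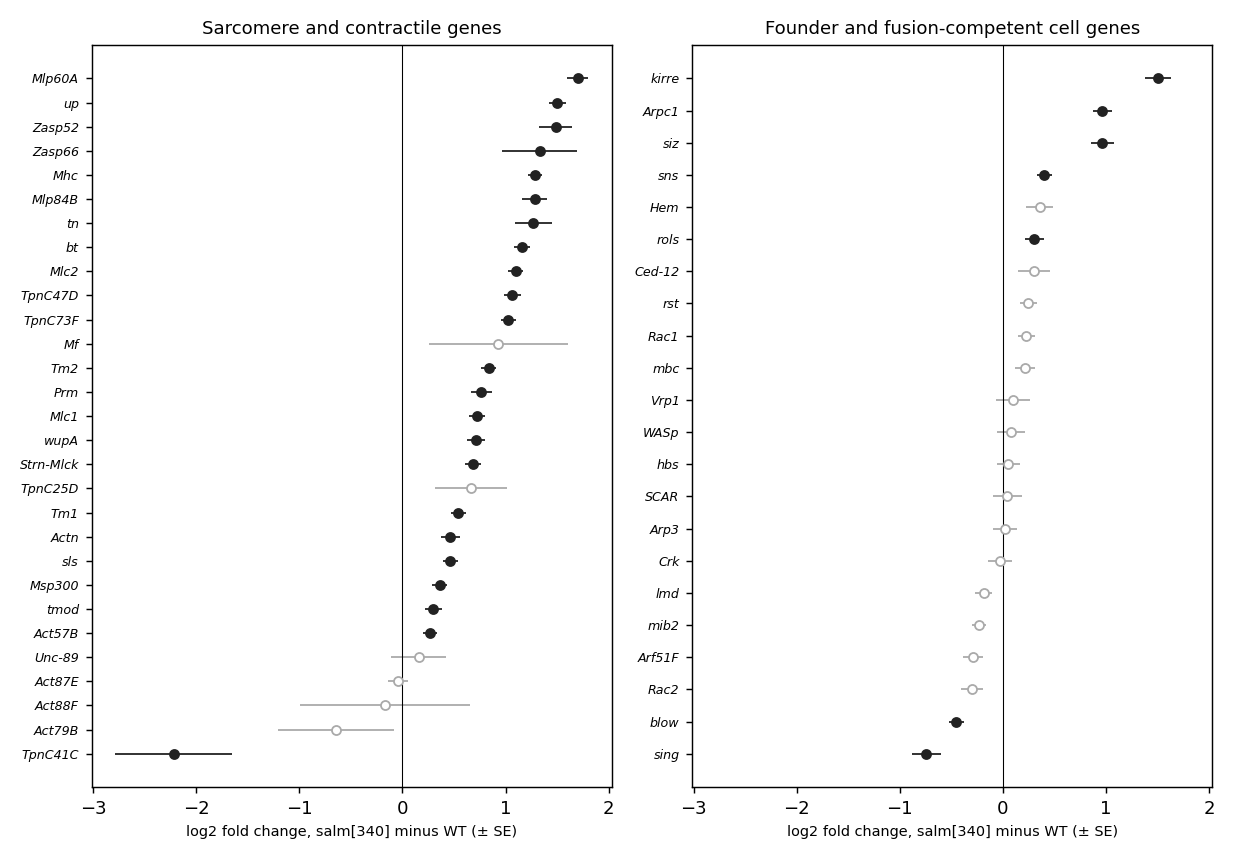
Log2 fold change (salm[340] minus WT, TMM scaling, error bars SE from the fit) of each sarcomere and contractile gene (left) and each founder and fusion-competent cell gene (right). Filled points passed the edgeR test and open points did not. On the left 22 of 29 genes were higher, on the right 5 of 22 were higher and 2 lower.

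Among muscle identity and fusion genes, single members changed. Of 23 founder identity factors, 6 were higher and 0 lower (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.21): salr, kn (log2 fold change 0.99), org-1 (0.94), Ptx1 (0.68), eya (0.48) and sd (0.39). Of 22 founder and fusion-competent cell genes, 5 were higher and 2 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.386). The founder cell adhesion gene kirre rose from 23.5 ± 3.29 to 66.6 ± 5.37 CPM (log2 fold change 1.504, SE 0.123), with Arpc1 (0.97), siz (0.96), its fusion-competent partner sns (0.40) and rols (0.31), and blow (-0.45) and sing (-0.74) fell. Among 21 early mesoderm regulators, 6 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.167), with Him (0.73), stumps (0.67) and zfh1 (0.58) higher and snail (sna), a transcription factor of the early mesoderm, lower (-1.16, 36.1 ± 1.56 to 16.1 ± 2.35 CPM, SD, n = 2 each). The general muscle factor Mef2 did not pass (0.10, SE 0.0784, adjusted p = 0.437 in edgeR). Of 12 Hox genes and cofactors, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.167): tsh (1.13, SE 0.0799), hth (0.91) and abd-A (0.56), while Antp was at 0.34 and did not pass. Of 7 fibrillar flight muscle genes, 1 was higher (Strn-Mlck, 0.68) and 1 lower (Gpdh1, -0.54), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.386), and bru1 (1.09, adjusted p = 0.107 in edgeR) did not pass. The mitochondrial share was higher in the same libraries, and with library size alone 1 of the identity factors was called higher and 17 lower.

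Single signalling genes changed. In the Notch list, 5 of 23 were higher and 3 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.994). The Notch inhibitor numb rose (1.14, 26.9 ± 0.348 to 59.0 ± 12.1 CPM, SD, n = 2 each) and the Notch target genes E(spl)mdelta-HLH (-0.84), E(spl)mgamma-HLH (-0.78) and E(spl)m3-HLH (-0.50) fell, while E(spl)mbeta-HLH, another target, rose (0.30). Of 20 receptor tyrosine kinase genes, 5 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.282), among them kek1 (1.09), rho (0.89) and Egfr (0.58). Of 25 Wingless, Dpp and Hedgehog genes, 6 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.194), with nkd (0.77), slp1 (0.66) and shn (0.56) higher and brk, a repressor of Dpp targets, lower (-0.64). Cell cycle genes split, with 3 of 27 higher and 3 lower (3 and 3 adjusted over the list alone, camera adjusted p = 1): aurB rose (1.36), and Orc1 (-0.93), dap (-0.53) and RnrL (-0.55) fell. Of 33 muscle attachment and guidance genes, 3 were higher and 2 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.432), including rhea, which encodes talin (0.61), drl (0.58), dnt (0.44) and robo1 (-0.42).

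The heat shock and dissociation stress list had 12 of 28 genes higher and 3 lower (12 and 3 adjusted over the list alone). Hsp68 rose from 122.5 ± 2.30 to 243.7 ± 1.06 CPM (log2 fold change 0.99, SE 0.0727) and Hsp70Aa from 565.4 ± 13.5 to 967.2 ± 15.2 CPM (0.77, SE 0.0676; SD, n = 2 each), with Hsp70Ba (1.08) and Hsp70Ab (0.79) among the near-identical copies that share fragments. Camera gave adjusted p = 0.0114 at the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.822) and without salm340 replicate 1 (adjusted p = 0.075). Fry did not pass (adjusted p = 0.0652). With library size alone 0 members were called higher and 27 lower, in a setting where 8277 of all 10738 tested genes were called lower. These are again the libraries with the higher mitochondrial share. With TMM scaling and mitochondrial genes left out, a fit chosen after seeing the data, camera at the preset correlation gave adjusted p = 0.015.

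Markers of other cell types gave no list-wide call in camera or in fry for one direction. In fry for either direction, 25 of the 26 lists passed, all but the sex dosage genes (adjusted p from 0.00065 to 0.0246). Among all 10738 tested genes, 3338 had an unadjusted p under 0.05 in edgeR. A pass in either direction is therefore not particular to a list or a cell type. Hemocyte markers had 3 of 17 higher and 4 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.597), with the crystal cell gene PPO2 (1.30) and glob1 (0.75) higher and drpr (-0.65) and Ppn (-0.60) lower. Neural markers had 3 of 29 higher and 2 lower (3 and 3, adjusted p = 0.854), including nerfin-1 (-0.70), wor (-1.06), scrt (0.61) and SoxN (0.60). Epidermis and ectoderm markers had 2 of 23 higher and 3 lower (2 and 3, adjusted p = 1), with cora (0.87) and pyd (0.75) against Nrx-IV (-0.48) and crb (-0.35). In these lists and the next ones the second pair of counts is adjusted over the list alone and the p is from camera. Visceral muscle had 2 of 11 higher and 0 lower (2 and 1, adjusted p = 0.491), both through genes of other lists, org-1 and Hand. Heart had 2 of 14 higher and 0 lower (2 and 0, adjusted p = 0.324), Hand (0.61) and Hr3 (0.31). Fat body had 0 of 8 higher and 1 lower (0 and 2, adjusted p = 0.977), Mtp (-1.32). Trachea had 1 of 15 higher and 1 lower (1 and 1, adjusted p = 0.854), knrl (1.96) and verm (-0.31). Gut and endoderm had 1 of 16 higher and 0 lower (0 and 0, adjusted p = 0.994), Ptx1. Salivary gland had 1 of 10 higher and 1 lower (1 and 1, adjusted p = 0.386), sano (0.52) and eyg (-1.43). Germ cells had 1 of 9 higher and 0 lower (1 and 0, adjusted p = 0.491), vas (1.40). Tendon cells had 1 of 6 higher and 0 lower (1 and 0, adjusted p = 0.432), how (0.46). Segmentation and early embryo genes had 3 of 21 higher and 2 lower (3 and 3, adjusted p = 0.491), with Dl (0.59) and slp1 higher and Sry-alpha (-0.77) and h (-0.66) lower. Late embryo genes had 1 of 15 higher and 2 lower (1 and 5, adjusted p = 0.386), obst-B (1.56) against TwdlV (-3.03) and verm. Of 6 sex dosage genes, 0 passed in edgeR or in DESeq2 (0 and 0, camera adjusted p = 0.854). None of them had an unadjusted p under 0.05 in edgeR, where msl-2 came closest (-0.28, SE 0.164).

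By position, genes on 2L, the arm of salm, were called more often than genes elsewhere (397 of 2006, 19.8% against 16.5%, odds ratio 1.25, Fisher's exact test, two-sided, adjusted p = 0.003413 over 8 tests), and X-linked genes less often (14.8% against 17.5%, odds ratio 0.814, adjusted p = 0.01665). Genes within 2 Mb of salm were not called more often than the rest of the arm (19.6% against 19.8%, adjusted p = 1). Without the histone genes, whose near-identical copies share fragments in a cluster on 2L, the share on 2L was 18.0% against 16.5% (odds ratio 1.12, Fisher's exact test, adjusted p = 0.4055) and neither arm passed, as X had an adjusted p of 0.1287.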

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

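The tests of myoblast share, embryo age and nuclear mRNA yield were written after the result they weigh had been seen. The tests of length and abundance, of both mitochondrial genomes, of overlapping genes and of transposons were written before, but the filter on transposon families was chosen after a first result without it had been seen.

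Features outside the gene table, which the comparison above did not use, also differed between the lines. Among 101 transposon families with at least 2 annotated insertions and 100 counts, summed and scaled like the genes, 31 were higher and 22 lower in salm[340] (edgeR, adjusted p under 0.05), and 11 differed at least 4-fold. The filter also dropped families named only by an identifier. In the first result, without it, 122 families were tested, 43 higher and 25 lower, and 14 differed at least 4-fold (11 higher, 3 lower). With the filter, the higher ones were gypsy (log2 fold change 3.83, from 20.6 ± 1.63 to 293.8 ± 18.5 CPM, SD, n = 2 each), 17.6 (3.45), accord2 (3.22), gypsy5 (2.94), NOF (2.86), diver2 (2.69), HMS-Beagle2 (2.305) and roo (2.15). The lower ones were invader3 (-3.29), G2 (-3.27) and Tirant (-2.70). A fragment matching many insertions was counted for each, so these levels are not comparable between families. Whether fragments of a family matched equally many insertions in both lines was not tested. The counts of a family are thus not separate fragments, which its p-value assumes. The 22 mitochondrial tRNA genes had a median of 2.12, above the control libraries like the other mitochondrial transcripts, and 11 of them passed. Fragments touching several features were counted for each. The tRNA counts may therefore hold fragments of neighbouring mitochondrial transcripts, which was not tested, and need not be a separate change.

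Of 29 sarcomere and contractile genes, 22 were higher in salm[340], 1 was lower and 6 did not pass, with a median of 0.72. The camera call was lost with an estimated correlation (adjusted p = 0.822), fry against no change did not pass (adjusted p = 0.0652), and 0 members passed in edgeR without either WT library. A trend with gene length or abundance is argued against: the median lay at the 100th percentile of 10000 random lists matched on both. Those lists had a median of 0.0438 and an upper bound set at 0.229. Members of random lists need not vary together, while the sarcomere genes had an estimated correlation of 0.184. The percentile thus does not exclude a joint shift of these genes by chance between the libraries. A higher share of myoblasts in the sort stays open. The founder and fusion-competent cell genes had a median of 0.0859 (bootstrap interval -0.0307 to 0.301), lower than the sarcomere genes (one-sided permutation p = 5e-04). As a set they thus rose less, which met the rule written against this explanation. That rule was written after the result had been seen, and the permutation treats genes as independent, so it does not decide the question. Their list had 5 of 22 genes higher (kirre at 1.504) and 2 lower, and was not made to measure myoblast share. Older embryos in the salm[340] collection stay open. Of the late embryo genes 3 were called, 2 of them lower, under the 4 calls set for a decision. Adjusted over the list alone, 5 were lower and 1 higher, but 3 of the 5 (TwdlV, Cpr56F and Cpr64Ad) averaged only 1.06 to 2.04 CPM in WT. Late embryo genes such as verm, serp and pio are also trachea markers, so the list need not follow the age of sorted myoblasts. The segmentation genes, which would fall in older embryos, had 3 higher and 2 lower. An effect of the salm[340] genotype on these genes was not tested, and cannot be told apart from embryo age or myoblast share with these libraries.

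Mitochondrial and rRNA transcripts were higher in salm[340]. A rise of mitochondrial gene expression from both genomes is argued against as the cause of a median of 2.60, because 141 nuclear genes of the mitochondrial ribosome and respiratory chain had a median of 0.37 (bootstrap interval 0.309 to 0.416), under the 0.5 set beforehand. The 68 respiratory chain genes alone had 0.417 (bootstrap interval 0.3519 to 0.5177), with an upper end past 0.5 but far below 2.60. A lower yield of nuclear mRNA in the salm[340] libraries stays open. The rRNA features are part of the pattern and cannot decide it, and of 117 snRNA and snoRNA genes, which carry no poly(A) tail either, 0 had at least 10 CPM without overlapping another gene. The 117 had a median of -0.305 and the 5 without overlap, at most 3.873 CPM, one of 1.37. An effect of the genotype on RNA content was not tested and stays open.

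With rRNA features left out, a set of 14 nuclear genes was nearly absent in only 1 of the lines (called, at least 8-fold, at least 10 CPM in the higher line, both libraries of that line above both of the other), 7 in each direction, on 5 arms, none nearer to salm than 5293 kb on 2L. Sharing of fragments with a gene overlapping in position is argued against: 0 of the 14 overlapped a called gene changed in the same direction. Fragments shared between near-identical copies were not tested. Within 1 kb of another of the 14 lay 4 genes (Cyp4p1 and Cyp4p2, CG42831 and lncRNA:CR45247), so the 14 may not be separate changes. Neighbours outside the 14 were not counted. CG11825 (2R, 10420414 to 10423650), which rose, lies near Prx2540-2 (2R, 10418718 to 10419761), which fell (-2.56). Differences between the lines outside salm stay open: 11 transposon families differed at least 4-fold, but the line and the salm genotype are the same contrast and cannot be told apart for these genes.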

How the results depend on the processing

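The fits without mitochondrial genes, without rRNA genes, on protein-coding genes and on thinned counts, the arm test without histone genes and the transposon family filter (14 families at least 4-fold apart without it against 11), were chosen after seeing the data. Of 1847 calls, 1844 were shared with DESeq2 size factors, 1739 with upper-quartile scaling, 1433 with DESeq2 (1443 calls) and 1594 with thinned nuclear counts (1686 calls). The fit without mitochondrial genes shared 1817 (1855 calls).

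With library size only, 8361 genes were called (84 higher, 8277 lower), 6558 at least 2-fold (55 and 6503), and camera on the heat shock list gave adjusted p = 0.79 in the other direction; the construction shifts the median gene by -1.19. Without a filter 1208 genes were lower, 338 at least 2-fold, with more genes tested (14972). With glmTreat, a stricter test, 385 genes were called, 275 higher and 110 lower. For the other changes the cause was not tested. Leaving out 1 library gave 14 to 3803 calls (14 to 1915 higher, 0 to 1888 lower) and 14 to 1199 at least 2-fold (14 to 577 higher, 0 to 622 lower), and salm from 1.87 to 1.94. Sxl, which did not pass at 0.03, changed sign under upper-quartile scaling (-0.00718), without a filter (-0.00604) and when a library was left out (-0.17 to 0.18), as did tra (-0.30 to 0.0776) and lncRNA:roX1 (-0.20 to 0.0883) when a library was left out. Sxl passed without salm340 replicate 1 (0.184, adjusted p = 0.0281) and lncRNA:roX1 without salm340 replicate 2 (-0.2027, adjusted p = 0.00709).

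Among genes changed at least 2-fold, the arm 2L had an odds ratio of 1.878 (adjusted p = 6.549e-09) against 1.253 among all calls, and X had 0.725 (adjusted p = 0.05695). Without histone genes, 2L had 1.12 and X 0.839, and 1.275 and 0.815 among genes changed at least 2-fold (adjusted p = 0.2966 and 0.5317), so the 2L call ended there.

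The replicate numbers share only a number: deviations of same-numbered libraries correlated at 0.0417 across genes, and the replicate block gave 2256 calls (1238 higher, 1018 lower), 617 at least 2-fold. Of 96 named genes called, 96 kept their direction in every fit that tested them (glmTreat was read for counts only). With library size only, direction was read relative to the median gene, and 38 rises had the opposite sign unadjusted. The fits reuse the libraries in which these genes were called, so a kept direction is not an independent check. Nor does a kept direction mean a kept call. Nuclear depth in salm[340] (5772320 to 5931283 counts) limits weakly expressed genes.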

Other observations

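The tests of gene families by name were chosen after the main results were seen; the oenocyte genes were listed before their values were seen.

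Genes of the cytoplasmic ribosome and of the respiratory chain were often higher in salm[340], in the libraries with the higher mitochondrial share (60.9% and 63.2% against 24.8% and 29.3%) and more nuclear rRNA (2.60% and 2.51% of nuclear counts against 0.768% and 0.591%). None of the nuclear genes among them was called when either WT library was left out. Of 90 cytoplasmic ribosomal protein genes, 71 were higher in salm[340] and 1 lower (edgeR, adjusted p under 0.05), with a median log2 fold change of 0.42 (bootstrap interval 0.36 to 0.47), and 40 of 68 nuclear respiratory chain genes were higher and 0 lower (median 0.42). Mitochondrial ribosomal protein genes were higher in 15 of 73 and lower in 1 (median 0.27), and proteasome subunits in 4 of 33 (median -0.0056). Replication-dependent histone genes had 55 of 115 members higher and 1 lower (median 1.08), but their near-identical copies share fragments and are not separate measurements. With library size alone the median of all genes moved by -1.19, so these medians are relative to the bulk of genes. Of 39 cytochrome P450 genes, 6 were higher and 4 lower, from -3.53 (Cyp4g1) to 9.86 (Cyp4p2).

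Cyp4g1 is a gene of oenocytes, cells whose formation needs salm, and was lower in salm[340] (-3.53). Less RNA from oenocytes in the salm[340] sort may account for it. Of 6 other oenocyte genes, 1 was called lower, FASN3 (-2.15, from 5.45 ± 0.211 to 1.22 ± 0.480 CPM, SD, n = 2 each, edgeR adjusted p = 0.004402), and 0 higher. Hnf4 (-0.65), FASN2 (-0.72), Cpr (-0.35), svp (-0.17) and FarO (0.28) did not pass. The median of the 6 was -0.50 with a bootstrap interval of -1.43 to 0.0550, which leaves the hypothesis open, and several of these genes are also used by other cells. A sort for myoblasts should remove oenocytes, but how many remained in either line was not measured. In WT, Cyp4g1 and FASN3 averaged 17.7 and 5.45 CPM.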
